A study of Bacillus subtilis with 15 samples.

How the data were processed

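RNA was measured in 15 samples of Bacillus subtilis strain AG174, 5 independent cultures per pH (6.0, 7.0 or 9.0). Per the labels, overnight cultures were diluted into baffled flasks of buffered medium and grown with shaking at 260 rpm. RNA was stabilised and purified with commercial kits (RNAprotect and RNeasy), and biotin-labelled cDNA was hybridised to Affymetrix antisense arrays of Bacillus subtilis, 1 array per culture. The deposited intensity values were made by the authors with the Affymetrix software GCOS, per the submitters' processing notes. Its version, algorithm and scaling target are not given in the sources used here. The values were linear signals, 1 per probe set and array, never negative, with 9 values at 0. The mean after trimming 2 percent from each end was between 998.9 and 999.6 on every array, so the arrays had been brought to a common scale before deposit. No array was pooled or left out, and no column belonged to samples of other series. The groups and replicate numbers were taken from the sample titles. No scan date or array batch was analysed here.

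Of 5033 probe sets, 4385 were for genes (4345 protein, 40 tRNA), 606 for intergenic regions and 42 were controls. Only gene probe sets entered the comparisons of genes and lists, and intergenic ones were tested apart from them. Each had 1 gene symbol: for 2978 it came from the platform annotation, and for the other 1407 it was the gene part of the probe set identifier. In 4 of the annotated cases the 2 symbols differed. The symbols are those of the array's design and many are old; the current name is given in parentheses at first use where it is well established. There were 4136 distinct symbols, 2796 of which were found in a reference gene table of the organism. For 83 symbols more than 1 probe set existed, 332 probe sets in all, and these were tested separately. A total of 74 gene probe sets were of kinds that can share probes with other transcripts. No genome sequence was used here, and no coordinates are given.

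Signals were log2 transformed, with the 9 zeros set to 0.1, the smallest positive value, and each array was centred on the median of its gene probe sets. Differences between groups were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with all 15 arrays in a single model without covariates, a two-sided test and Benjamini-Hochberg adjustment over the 4385 gene probe sets. A change was called at an adjusted p under 0.05. The prior degrees of freedom were 6.55. Fold values are antilogs of the centred log2 changes, and mean signals are arithmetic means of the deposited values. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. For dim genes the log2 change depends on values near the background, where the median intergenic signal was 33.8, so changes are also given with a pseudocount of 27.7 (the 10th percentile of gene signals) where that moved them by more than 1.5 times.

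The tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The 38 lists held 889 genes, 857 of which were found on the array. Each list was tested in each comparison with camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 114 tests. Camera compares the members of a list with all other genes. A list's counts of changed members use the adjustment over all genes unless the text says otherwise. With the correlation estimated from the arrays, 2 of the 56 calls held, both for anaerobic and nitrate respiration at pH 9.0. The genes named for the first comparisons are the 10 probe sets with the largest rise and the 10 with the largest fall among those that passed, had no overlap between the values of the 2 groups, had 1 symbol and had a mean in the brighter group above the 25th percentile. For pH 9.0 against pH 6.0 these were the 5 largest in each direction. For each list described, up to 4 members with the largest change among those that passed are named, or up to 2 as values where none passed, and for changes at both extremes the 5 genes with the largest smaller change in each class of directions. Which lists without a call to describe, and the genes used in the tests of the SOS response, of a minority of cultures and of ResD, were chosen after their values were seen. Where every array of the dimmer group was at or below its median intergenic signal, a fold is given with each array's median in place of the dimmer signal, as an antilog of a difference of mean log2 values. For yqgG at pH 9.0 against pH 7.0 only the values below the median were raised to it. These folds were also added after seeing the data.

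The procedure was tested on simulated arrays with the real means and spreads, in which 200 of 4385 probe sets were changed. For pH 6.0 against pH 7.0 it recovered 44.1, 80.9 and 95.3 percent of changes of 0.5, 1 and 2 on the log2 scale, and 3.31 percent of its calls were false. For pH 9.0 against pH 7.0 these were 69.4, 82.9, 98.4 and 4.02 percent, and for pH 9.0 against pH 6.0 they were 48.5, 85.5, 94.3 and 3.18 percent. Each comparison was simulated once with the same spreads and array numbers, so differences between their percentages come from the random draws. In the simulation of pH 6.0 against pH 7.0 the list test called all 5 lists shifted by 0.5, and none of the 29 lists that shared no gene with them. The simulated noise was drawn independently for each probe set. The simulation therefore cannot show how often the list test makes false calls where genes are correlated. Alternatives tried were quantile normalization, values as deposited, a pseudocount, removal of dim probe sets, the replicate number as a block, only the groups compared in the model, no intensity trend, array weights, a 2-fold minimum, each array left out in turn, an estimated correlation, and fry, which tests whether a list's genes move one way on balance. A further 3 were added after seeing the data: 1 value per gene, values as deposited without pH 9.0 replicate 3, and leaving out arrays of the group outside a comparison.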

Results

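Transcript levels of Bacillus subtilis strain AG174 were compared between aerated cultures grown in medium buffered at pH 6.0, 7.0 or 9.0. For each pH, 5 independent cultures were grown at 37 °C in potassium-modified LB with 50 mM HOMOPIPES as the buffer and harvested at an optical density of 0.2. Each culture gave 1 Affymetrix array, 15 arrays in all. The arrays carried 4385 gene probe sets, of which 4345 were for protein genes and 40 for tRNA genes. They also carried 606 probe sets for intergenic regions and 42 controls. Each array had been scaled by the authors to nearly the same mean, with a trimmed mean signal between 998.9 and 999.6. The number of arrays limits the precision, and the median standard error of a log2 change was 0.128.

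Cultures of the same pH resembled each other closely. Correlations of log2 signals across genes, which are not independent replicates, ran from 0.993 to 0.996 within pH 6.0 and from 0.990 to 0.994 within pH 7.0. Between pH 9.0 and pH 6.0 they fell to between 0.911 and 0.920 once pH 9.0 replicate 3 was set aside. That array stood apart at the dim end of its range. Its 5th percentile of gene signal was 126.7, against 11.7 to 18.4 on the other 14 arrays, and its median intergenic signal was 225, against 22.4 to 42.2. Its correlations brought the lowest value within pH 9.0 to 0.928, against 0.992 without it. Foreign control probe sets on it had a median signal of 3.3, inside the range of 1.8 to 4.5 on the others. All 15 arrays entered every comparison. Without this array 0 lists lost their call and 6 list tests passed that had not passed with it. These were glycolysis, heat shock proteins, thiol stress and the biofilm matrix at pH 6.0 against pH 7.0, and motility and cation antiporters at pH 9.0 against pH 7.0.

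**Figure D1:**
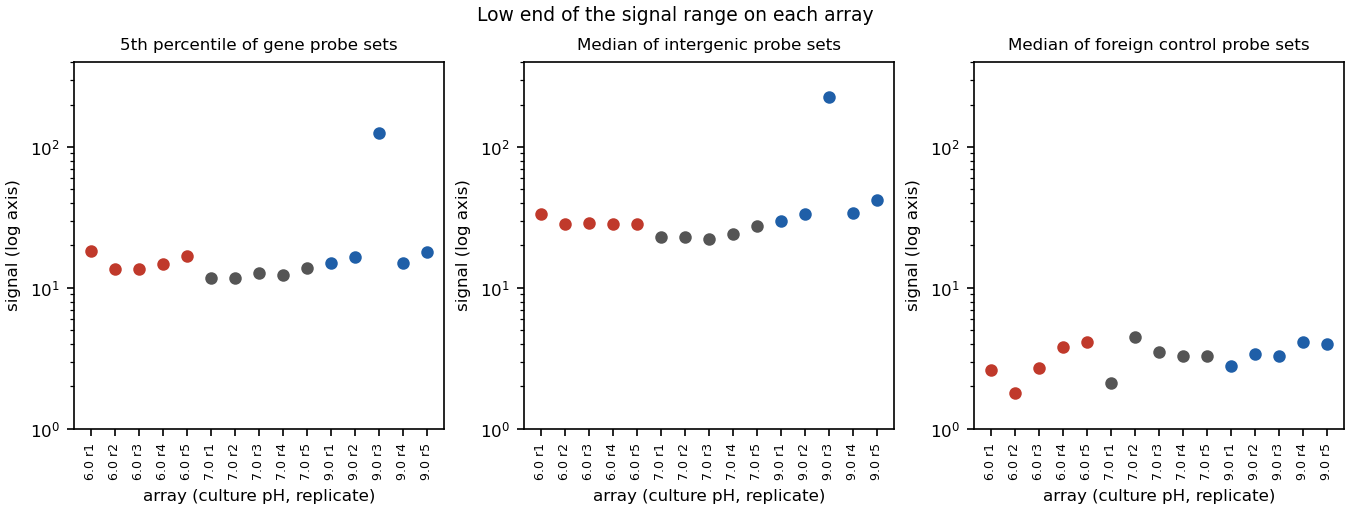
Each point is 1 array, with the culture pH and replicate on the horizontal axis and signal on a log axis, for the 5th percentile of gene probe sets, the median of intergenic probe sets and the median of foreign control probe sets. The array of pH 9.0 replicate 3 lies at 126.7 and 225 in the first panels and at 3.3, among the others, in the last.

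The comparison of pH 6.0 with pH 7.0 asked which transcripts change in mild acid. The largest rises were in ysbA and ysbB, which encode a pyruvate transporter, and in yvgW (now cadA), a metal-exporting ATPase. The signal of ysbA (BG12311) was 4240.1 ± 216 at pH 6.0 and 203 ± 50.9 at pH 7.0 (mean ± SD, n = 5), a 20.7-fold difference with a log2 change of 4.37 ± 0.30 (SE, adjusted p = 3.9e-10). That of yvgW (BG14105) was 2339 ± 89.3 against 114 ± 10.1, 19.8-fold higher in acid, and ysbB was 19.6-fold higher. Acetolactate synthase alsS was 10.6-fold higher, and the general stress genes yflT and gsiB were 10.7-fold and 10.5-fold higher. The largest falls were in the late genes of the defective prophage PBSX, among them xkdG, xkdI and xhlA, in the mannitol transporter gene mtlA and in the surfactin synthetase gene srfAA.

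In all, 2006 of 4385 gene probe sets changed (limma, Benjamini-Hochberg adjusted p under 0.05), 1143 higher and 863 lower at pH 6.0. Of these, 662 differed at least 2-fold, 349 higher and 313 lower. Without pH 9.0 replicate 3, whose spread enters the shared variance, 2911 changed. Each array was centred on its median gene signal, and without centring each log2 change lay 0.054 higher. The signal of xkdH at pH 6.0 was 3.4 to 4.7, below the median intergenic signal on all 5 arrays. With that median in place of its signal it was 8.75-fold lower. This value is set by the background, so the fall of xkdH cannot be ranked against those of xkdG, xkdI or xhlA. Dim genes depend on how the low end is treated: with 27.7 added to every signal, the log2 change of xkdH went from -5.99 to -3.16, that of ybdT from 3.79 to 2.03, that of yosK from 3.42 to 2.37, that of yxcC from 3.35 to 2.40, that of xkdX from -3.22 to -2.63 and that of trkA from 3.35 to 2.70. All of them remained past the threshold.

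Stress regulons moved in opposite directions in acid. In the general stress regulon of sigma factor SigB, 41 of 44 probe sets rose, 1 fell and 2 did not pass the test, and 41 rose and 1 fell adjusted over the list alone. The median log2 change was 1.84 (adjusted p = 2.9e-16, adjusted p = 0.131 with an estimated correlation). Leading members were yflT at 3.42 ± 0.25 (adjusted p = 8.5e-10), gsiB at 3.39 and yjgD at 3.12, the last at 2.48 with the added 27.7. The SigW regulon, which responds to envelope stress, fell: 1 of 45 probe sets rose, 39 fell and 5 did not pass, with a median log2 change of -1.35 (adjusted p = 2.7e-21, adjusted p = 0.131 with an estimated correlation). Adjusted over the list alone, 1 rose and 39 fell. Its leading members were ydjF (now pspA), a phage shock protein, at -2.65 ± 0.13 (adjusted p = 3.0e-12), ydjH at -2.45 and ydjG at -2.35. The SigM regulon, also an envelope stress regulon, rose instead, as 15 of 22 probe sets rose, 0 fell and 7 did not pass (median log2 change 0.54, adjusted p = 7.3e-05, adjusted p = 0.354 with an estimated correlation), and 15 rose and 0 fell adjusted over the list alone. It was led by yqjL at 1.23, ydaH (now amj), a lipid II flippase, at 1.12 and ywaC (now sasA), a (p)ppGpp synthetase, at 1.10.

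Metal transport genes also responded. Among metal efflux genes, 10 of 15 probe sets rose, 0 fell and 5 did not pass, with a median log2 change of 0.34 (adjusted p = 0.000375, adjusted p = 0.11 with an estimated correlation), and 10 rose and 0 fell adjusted over the list alone. The members with the largest rises were yvgW at 4.31 ± 0.11 (adjusted p = 6.9e-16), czcD, a cation exporter, at 2.97 and trkA (now czcO) at 3.35, the last at 2.70 with the added 27.7. Genes of the iron-responsive Fur regulon fell, as 2 of 38 probe sets rose, 27 fell and 9 did not pass (median log2 change -0.46, adjusted p = 5.3e-10, adjusted p = 0.453 with an estimated correlation). Adjusted over the list alone, 2 rose and 27 fell. The siderophore synthesis genes dhbC and dhbE were at -2.18 and -2.16, and the flavodoxin gene ykuN was at -2.01 ± 0.13 (adjusted p = 2.0e-10).

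Genes for using sugars and for respiration were lower at pH 6.0. For carbohydrate and glycerol use, 4 of 46 probe sets rose, 37 fell and 5 did not pass, and 4 rose and 37 fell adjusted over the list alone. The median log2 change was -1.54 (adjusted p = 1.0e-13, adjusted p = 0.192 with an estimated correlation). The mannitol genes mtlA and mtlD were at -3.37 ± 0.18 (adjusted p = 7.5e-12) and -2.91, and the phospho-beta-glucosidase gene bglH was at -2.56. For the proton-translocating ATP synthase, none of 9 probe sets rose, 9 fell and 0 did not pass (median log2 change -0.87, adjusted p = 6.6e-05, adjusted p = 0.453 with an estimated correlation), and the counts were the same adjusted over the list alone. Its members atpC, atpD and atpI were at -0.99, -0.96 and -0.91, and the list's median was -0.58 after quantile normalization. In the respiratory chain, none of 31 probe sets rose, 17 fell and 14 did not pass (median log2 change -0.50, adjusted p = 3.4e-06, adjusted p = 0.455 with an estimated correlation), and 0 rose and 17 fell adjusted over the list alone. Cytochrome c550 (cccA) was at -1.90 ± 0.14 (adjusted p = 6.5e-10), and the cytochrome c reductase genes qcrC and qcrA were at -1.83 and -1.67. Among genes of anaerobic and nitrate respiration, none of 16 probe sets rose, 12 fell and 4 did not pass (median log2 change -0.86, adjusted p = 4.1e-05, adjusted p = 0.0987 with an estimated correlation), and 0 rose and 12 fell adjusted over the list alone. The regulator gene fnr was at -1.31 ± 0.13 (adjusted p = 1.0e-07). Both narG probe sets for nitrate reductase are counted among the falls but were not above the intergenic median on any pH 6.0 array, and with that median as their level 1 was 2.06-fold lower and the other not lower (ratio 0.972).

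Biosynthetic groups moved both ways. Branched-chain amino acid synthesis rose, as 10 of 11 probe sets rose, 0 fell and 1 did not pass (median log2 change 1.11, adjusted p = 6.4e-05, adjusted p = 0.307 with an estimated correlation), and 10 rose and 0 fell adjusted over the list alone. The acetohydroxy acid synthase genes ilvB and ilvN were at 2.56 ± 0.29 (adjusted p = 3.5e-07) and 1.68, with ilvB at 1.73 after the added 27.7, and ilvC was at 1.62. Fatty acid and phospholipid synthesis fell: none of 19 probe sets rose, 13 fell and 6 did not pass (median log2 change -0.38, adjusted p = 0.00632, adjusted p = 0.714 with an estimated correlation), and 0 rose and 13 fell adjusted over the list alone. Its largest change was in yhfB (now fabHB), which starts fatty acid chains, at -0.82 ± 0.10 (adjusted p = 7.0e-07), followed by yjbW (now fabI) at -0.52 and accB at -0.50. For purine synthesis, none of 17 probe sets rose, 7 fell and 10 did not pass (median log2 change -0.18, adjusted p = 0.027, adjusted p = 0.591 with an estimated correlation), with purK at -0.69, purE at -0.64 and purB at -0.48, and 0 rose and 7 fell adjusted over the list alone. The purine call ended without pH 7.0 replicate 1 (adjusted p = 0.0642) and when dim probe sets were removed (adjusted p = 0.0651). Motility and chemotaxis rose slightly: 19 of 56 probe sets rose, 0 fell and 37 did not pass (median log2 change 0.19, adjusted p = 0.013, adjusted p = 0.793 with an estimated correlation), and 16 rose and 0 fell adjusted over the list alone. It was led by the chemoreceptor gene mcpC at 1.32 ± 0.09 (adjusted p = 3.0e-10) and by 2 probe sets of the autolysin gene lytD at 1.09 and 0.79. A set test that asks only whether members move one way (fry) gave this list an adjusted p of 0.0940. Leaving out pH 9.0 replicate 3 gave 32 rises and 5 falls.

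Among ribosomal proteins, 1 of 50 probe sets rose, 8 fell and 41 did not pass (median log2 change -0.30, adjusted p = 0.000808, adjusted p = 0.778 with an estimated correlation), and 1 rose and 1 fell adjusted over the list alone. The ribosomal call ended under quantile normalization (median -0.0031, adjusted p = 0.924), and fry gave an adjusted p of 0.0503. Without pH 9.0 replicate 3, 45 of the 50 fell. The probe sets named by rule were rplI at 0.52, rpsP at -0.50 and rpsB at -0.41. The change of rpsB did not pass without pH 6.0 replicate 2 (adjusted p = 0.0614), without pH 7.0 replicate 1 (adjusted p = 0.0504) or after quantile normalization (adjusted p = 0.0819).

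In the list of SOS and PBSX prophage genes, 9 of 43 probe sets rose, 29 fell and 5 did not pass (median log2 change -2.08, adjusted p = 2.7e-09, adjusted p = 0.329 with an estimated correlation), and 9 rose and 29 fell adjusted over the list alone. Prophage structural genes fell, with xkdG at -3.41 ± 0.17 (adjusted p = 2.8e-12), xkdI at -3.41 and xkdH, at background in acid, 8.75-fold lower with the intergenic median as its level. The prophage genes xhlA, xkdN, xkdX, xkdM and xkdJ, chosen by size of fall alone, ranged from -3.39 to -3.00. For antimicrobial peptides and polyketides, 8 of 81 probe sets rose, 26 fell and 47 did not pass, and 8 rose and 26 fell adjusted over the list alone. The signs differ here: the median log2 change was 0.05, the mean was -0.62 and the test called a fall (adjusted p = 0.000318, adjusted p = 0.307 with an estimated correlation), with the median at -0.06 under quantile normalization. Surfactin synthetase genes hold many of its probe sets, among them srfAA at -3.03 ± 0.14 and -2.92 and srfAB at -2.93, and with 1 value per gene the list's call ended (adjusted p = 0.282). Leaving out pH 9.0 replicate 3 gave 25 rises and 28 falls.

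Several metabolic lists changed in both directions without a call for the list. Among acetoin, lactate and acetate genes, 5 of 17 probe sets rose, 6 fell and 6 did not pass (adjusted p = 0.636), and 5 rose and 6 fell adjusted over the list alone. Its median log2 change was -0.16 and its mean 0.11. The acetoin synthesis genes alsS and alsD rose by 3.41 ± 0.13 (adjusted p = 2.9e-13) and 2.87, while lactate dehydrogenase lctE was at -1.29. For malate and C4-dicarboxylate metabolism, 5 of 20 probe sets rose, 9 fell and 6 did not pass (adjusted p = 0.341), and 5 rose and 9 fell adjusted over the list alone. The malate transporter gene yufR (now maeN) was at -2.97 ± 0.45 (adjusted p = 2.0e-05) and the C4-dicarboxylate transporter gene ydbH (now dctP) at -2.72. The regulator gene citT was at 1.32, or 0.72 with the added 27.7. It was dim at pH 7.0, at or below the median intergenic signal on 3 of 5 arrays. Among cation antiporters and potassium transporters, 5 of 20 probe sets rose, 6 fell and 9 did not pass (adjusted p = 0.92), and 5 rose and 7 fell adjusted over the list alone. The calcium-proton antiporter gene yfkE (now chaA) was at 2.52 ± 0.26 (adjusted p = 1.6e-07), or 1.90 with the added 27.7, and yheK (now nhaX) was at 1.97. Leaving out pH 9.0 replicate 3 gave 11 rises and 7 falls in that list. Among alcohol, aldehyde and formate dehydrogenases, 9 of 19 probe sets rose, 5 fell and 5 did not pass (adjusted p = 0.495), and 10 rose and 5 fell adjusted over the list alone. The aldo-keto reductase gene yhdN was at 2.20 and alanine dehydrogenase ald at 1.28, while 1 of the probe sets of the formate dehydrogenase gene yrhE was at -1.27.

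Calls for glycolysis and heat shock proteins at pH 6.0 depended on the arrays and the scaling. In glycolysis, none of 14 probe sets rose, 5 fell and 9 did not pass (median log2 change -0.21, adjusted p = 0.0567, adjusted p = 0.793 with an estimated correlation), and 0 rose and 4 fell adjusted over the list alone. It passed without pH 9.0 replicate 3, with 14 lower (adjusted p = 0.00135), as deposited (adjusted p = 0.00149), and with the added 27.7 (adjusted p = 0.0425). It also passed without pH 7.0 replicate 5 or pH 9.0 replicate 1 or 4 (adjusted p = 0.0483, adjusted p = 0.0479 and adjusted p = 0.0486). Under quantile normalization 6 rose and 2 fell (median 0.020, adjusted p = 0.598). Among heat shock proteins, none of 15 probe sets rose, 6 fell and 9 did not pass (median log2 change -0.20, adjusted p = 0.0753, adjusted p = 0.778 with an estimated correlation), and 0 rose and 6 fell adjusted over the list alone. That list passed without pH 9.0 replicate 3, with 1 higher and 8 lower (adjusted p = 0.024), and as deposited (adjusted p = 0.0331).

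The comparison of pH 9.0 with pH 7.0 asked the same of base. Genes of the phosphate transporter operon yqgG to yqgK (now pst) were among those with the largest rises. The signal of yqgG (BG11375), the phosphate-binding protein, was 2903 ± 623 at pH 9.0 and 19.7 ± 14.1 at pH 7.0 (mean ± SD, n = 5), a log2 change of 7.31 ± 0.40 (SE, adjusted p = 1.4e-11). At pH 7.0 it was at or below the median intergenic signal on 3 of 5 arrays, and with such values raised to that median it was 87.5-fold higher at pH 9.0. Cytochrome bd oxidase, a terminal oxidase with high oxygen affinity, rose as well, with cydA (BG11925) at 4277 ± 393 against 61.5 ± 12.5, 59.4-fold higher, and cydB 43.5-fold and cydD 25.8-fold higher. Pyrroline-5-carboxylate dehydrogenase rocA was 33.1-fold higher and yrkO 37.5-fold higher. The largest falls were in the malate transporter gene yufR (now maeN), in 3 probe sets of the formate dehydrogenase gene yrhE, which were 16.6-fold, 14.5-fold and 12-fold lower, in yhbI, yhbJ and yhcA, and in the malic enzyme gene ywkA (now maeA). The malate transporter gene yflS fell to background, so the size of its fall is open.

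In all, 2359 of 4385 gene probe sets changed, 944 higher and 1415 lower at pH 9.0, and 552 differed at least 2-fold, 369 higher and 183 lower. The split by direction depends on the scaling, and on the deposited scale, with no centring, 1452 were higher and 929 lower. Each log2 change lay 0.25 higher on that scale, and 0.15 higher without pH 9.0 replicate 3. Without that array 2802 changed, 1128 higher and 1674 lower, and 2310 of the 2359 were again called in the same direction. It also moves the fitted changes of dim genes, since yufR went from -6.35 to -6.98 and yflS from -5.62 to -6.60 without it. With 27.7 added to every signal these were -5.17 and -2.71, and the rises of yqgG, yqgH, yqgJ and yqgK were 5.75, 4.83, 5.06 and 4.85. Quantile normalization gave -6.25 for yflS. At pH 9.0 yufR and yflS were at or below the median intergenic signal on all 5 arrays, and with that median in place of their signal they were 45.3-fold and 4.56-fold lower on the fitted scale. The mean signals of yufR were 1921 at pH 7.0 and 56.2 at pH 9.0, the latter raised by replicate 3 at 207.8.

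**Figure D2:**
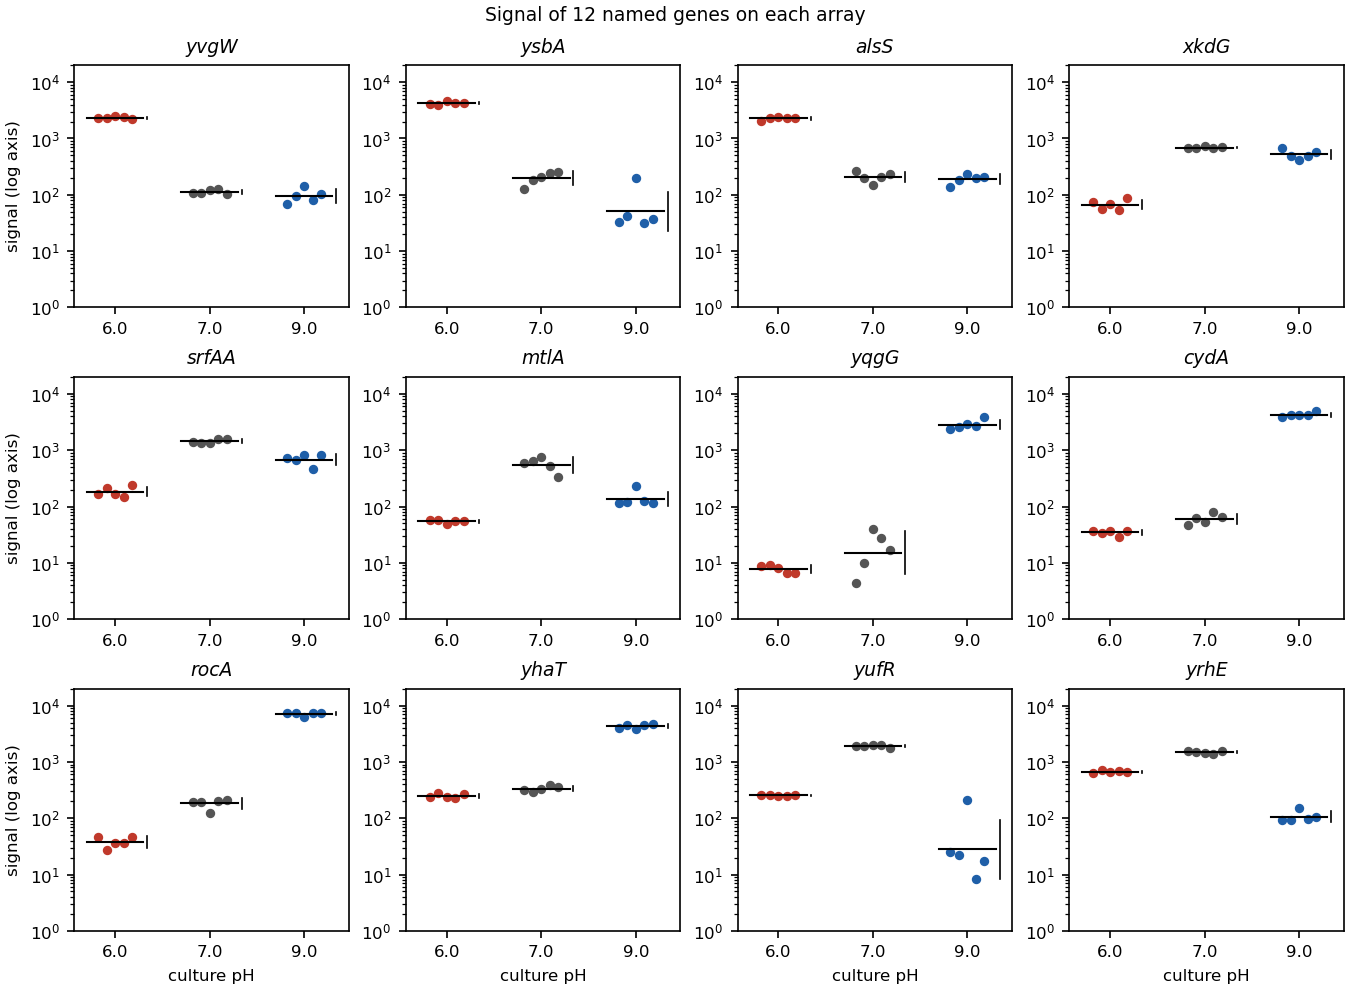
Signal of 12 named genes on a log axis against culture pH, where each point is 1 of 5 arrays per pH, the horizontal bar is the geometric mean and the vertical bar spans 1 SD of the log2 signal on either side. The panel srfAA shows the first of its probe sets. At pH 6.0 yvgW and ysbA had mean signals of 2339 and 4240.1, and at pH 9.0 cydA and rocA had 4277 and 7179.6.

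Respiratory genes rose at pH 9.0. Among genes of anaerobic and nitrate respiration, 16 of 16 probe sets rose, 0 fell and 0 did not pass, with a median log2 change of 1.88 (adjusted p = 1.4e-13), and 16 rose and 0 fell adjusted over the list alone. This call held with an estimated correlation (adjusted p = 0.00505). Its leading members were cydA at 5.89 ± 0.14 (adjusted p = 8.2e-17), cydB at 5.44 and the nitrite reductase gene nasD at 3.85. In the respiratory chain list, which shares cydA and cydB with it, 19 of 31 probe sets rose, 4 fell and 8 did not pass (median log2 change 0.57, adjusted p = 4.2e-05, adjusted p = 0.529 with an estimated correlation), and 19 rose and 4 fell adjusted over the list alone. Its other named member was cydD, needed to assemble cytochrome bd, at 4.69 ± 0.12 (adjusted p = 3.6e-16).

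Phosphate, arginine and pyrimidine genes rose too. In the PhoP regulon of phosphate starvation, 11 of 21 probe sets rose, 1 fell and 9 did not pass (median log2 change 0.54, adjusted p = 3.1e-05, adjusted p = 0.196 with an estimated correlation), and 11 rose and 1 fell adjusted over the list alone. The operon members yqgG, yqgH and yqgJ were at 7.31, 5.84 ± 0.21 and 5.84, or at 5.75, 4.83 and 5.06 with the added 27.7. For arginine and ornithine catabolism, 6 of 7 probe sets rose, 1 fell and 0 did not pass (median log2 change 2.26, adjusted p = 4.0e-06, adjusted p = 0.0957 with an estimated correlation), and 6 rose and 1 fell adjusted over the list alone. The genes rocA, rocB and rocD were at 5.05 ± 0.18 (adjusted p = 2.0e-14), 4.34 and 3.05, with rocB at 3.52 after the added 27.7. The list's score on pH 9.0 replicate 3 was 2.30, against 2.61 to 2.72 on the other pH 9.0 arrays. Pyrimidine synthesis rose, as 12 of 13 probe sets rose, 1 fell and 0 did not pass (median log2 change 1.62, adjusted p = 5.2e-08, adjusted p = 0.192 with an estimated correlation), and 12 rose and 1 fell adjusted over the list alone. The 2 probe sets of pyrAB, a carbamoyl phosphate synthase subunit, were at 2.50 ± 0.18 (adjusted p = 1.2e-09) and 2.36, or 1.69 and 1.75 with the added 27.7, and pyrAA was at 1.90.

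Nitrogen and sulfur lists rose with values that lean on pH 9.0 replicate 3. For nitrogen limitation and nitrate use, 10 of 24 probe sets rose, 3 fell and 11 did not pass (median log2 change 0.87, adjusted p = 0.00693, adjusted p = 0.102 with an estimated correlation), and 10 rose and 3 fell adjusted over the list alone. The median was 0.25 without that array. Nitrite reductase nasD, also in the anaerobic list, was at 3.85 ± 0.17 (adjusted p = 5.9e-13), nasE at 1.23 and nasF at 1.20. For cysteine, methionine and sulfur metabolism, 11 of 30 probe sets rose, 3 fell and 16 did not pass (median log2 change 0.61, adjusted p = 0.00117, adjusted p = 0.0957 with an estimated correlation), and 11 rose and 3 fell adjusted over the list alone. Its median was 0.15 without that array. The members with the largest rises were ylnD at 1.93 ± 0.14 (adjusted p = 1.3e-09), the regulator gene ytlI at 1.69 and ylnC at 1.51. In the Fur regulon, 18 of 38 probe sets rose, 3 fell and 17 did not pass (median log2 change 0.16, adjusted p = 5.3e-05, adjusted p = 0.639 with an estimated correlation), and 18 rose and 3 fell adjusted over the list alone. Without pH 9.0 replicate 3, 27 of its probe sets rose and the median was 0.30. The gene ykuO was at 2.35 ± 0.13 (adjusted p = 3.0e-11), and 2 probe sets of the siderophore synthetase gene dhbF were at 2.34 and 2.33. For the SigB regulon, 18 of 44 probe sets rose, 4 fell and 22 did not pass (median log2 change 0.35, adjusted p = 0.00397, adjusted p = 0.639 with an estimated correlation), and 18 rose and 4 fell adjusted over the list alone. The ribosome hibernation factor gene yvyD (now hpf) was at 2.78 ± 0.12 (adjusted p = 4.5e-13), ysnF at 1.27 and yhxD at 1.14. The SigB list scores of the 2 groups overlapped. They ran from -0.33 to 0.50 on the pH 7.0 arrays and from 0.21 to 0.80 on the pH 9.0 arrays. Replicate 3 gave the highest pH 9.0 score, and pH 7.0 replicate 4 exceeded pH 9.0 replicates 1, 4 and 5.

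The SigX regulon and genes of decarboxylases and polyamine synthesis fell. In the SigX regulon, whose genes modify the cell envelope, none of 18 probe sets rose, 16 fell and 2 did not pass (median log2 change -1.16, adjusted p = 1.3e-07, adjusted p = 0.307 with an estimated correlation), and 0 rose and 16 fell adjusted over the list alone. The sigma factor gene sigX was at -1.66 ± 0.12 (adjusted p = 1.7e-09), pbpX at -1.57 and csbB at -1.40. The SigW envelope stress regulon was not called: 6 of 45 probe sets rose, 18 fell and 21 did not pass (median log2 change -0.21, adjusted p = 0.268, adjusted p = 0.855 with an estimated correlation), and 6 rose and 18 fell adjusted over the list alone. Leaving out pH 9.0 replicate 3 gave it 11 rises and 18 falls, and as deposited 15 rose and 9 fell. Among decarboxylases and polyamine synthesis genes, none of 8 probe sets rose, 7 fell and 1 did not pass (median log2 change -0.85, adjusted p = 0.000468, adjusted p = 0.453 with an estimated correlation), and 0 rose and 7 fell adjusted over the list alone. The largest fall was in cad (now speA), arginine decarboxylase, at -1.53 ± 0.11 (adjusted p = 1.5e-09). Its other named members, psd at -1.25 and pssA at -1.17, are genes of phospholipid synthesis and belong to the SigX list too. For carbohydrate and glycerol use, 5 of 46 probe sets rose, 33 fell and 8 did not pass (median log2 change -0.54, adjusted p = 0.000363, adjusted p = 0.536 with an estimated correlation), and 5 rose and 33 fell adjusted over the list alone. The mannitol gene mtlA was at -2.25 ± 0.18 (adjusted p = 2.9e-09). The fructose transporter gene levD went the other way, at 2.28, or 1.51 with the added 27.7. So did levG, not above the intergenic median on any pH 7.0 array and 2.43-fold higher with that median as its level. In the carbohydrate list 8 rose and 34 fell without pH 9.0 replicate 3. For purine synthesis, none of 17 probe sets rose, 14 fell and 3 did not pass (median log2 change -0.39, adjusted p = 0.000445, adjusted p = 0.356 with an estimated correlation), and 0 rose and 15 fell adjusted over the list alone, with purK at -1.12, purE at -1.03 and purB at -0.80. In the SOS and PBSX list, 1 of 43 probe sets rose, 32 fell and 10 did not pass (median log2 change -0.52, adjusted p = 0.000322, adjusted p = 0.583 with an estimated correlation), and 1 rose and 33 fell adjusted over the list alone. The named members were tagC (dinC), an SOS gene, at 1.29, or 0.70 with the added 27.7, and the prophage genes xkdJ and xkdI at -0.78 and -0.73. For the SigX, decarboxylase and purine lists pH 9.0 replicate 3 had the lowest score of the pH 9.0 arrays, at -1.34, -1.33 and -0.63.

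A further set of lists fell only under some scalings. In glycolysis, none of 14 probe sets rose, 12 fell and 2 did not pass (median log2 change -0.56, adjusted p = 0.0027, adjusted p = 0.666 with an estimated correlation), and 0 rose and 12 fell adjusted over the list alone, with the call ending under quantile normalization (median -0.056, adjusted p = 0.555). The glucose transport genes ptsG, ptsI and ptsH were at -1.12 ± 0.14 (adjusted p = 1.7e-06), -0.78 and -0.75. Among ribosomal proteins, none of 50 probe sets rose, 45 fell and 5 did not pass (median log2 change -0.55, adjusted p = 2.2e-06, adjusted p = 0.666 with an estimated correlation), and 0 rose and 47 fell adjusted over the list alone, and under quantile normalization the list was not called and its test pointed upward (median -0.0072, adjusted p = 0.842). The genes rpsP, rpsS and rpmI were at -0.66, -0.63 and -0.61, and under quantile normalization rpsS and rpmI did not pass (adjusted p = 0.202 and adjusted p = 0.0504). In the PerR regulon of peroxide stress, none of 13 probe sets rose, 9 fell and 4 did not pass (median log2 change -0.45, adjusted p = 0.00117, adjusted p = 0.536 with an estimated correlation), and 0 rose and 9 fell adjusted over the list alone, with the call ending under quantile normalization (median -0.023, adjusted p = 0.223). Catalase katA was at -2.42 ± 0.10 (adjusted p = 3.2e-13), mrgA at -1.10 and ygaG (now perR) at -1.09. Among heat shock proteins, 2 of 15 probe sets rose, 12 fell and 1 did not pass (median log2 change -0.60, adjusted p = 0.0168, adjusted p = 0.676 with an estimated correlation), and 2 rose and 13 fell adjusted over the list alone, with the call ending under quantile normalization (median -0.16, adjusted p = 0.177) and when dim probe sets were removed (adjusted p = 0.110). The protease genes htrA and yvtA (now htrB) rose, at 1.31 ± 0.13 (adjusted p = 9.6e-08) and 0.78, while hrcA was at -0.79. On each of these 4 lists pH 9.0 replicate 3 had the lowest score of the pH 9.0 arrays.

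Lists of transporters and fermentation genes held large single changes without a call for the list. Among cation antiporters and potassium transporters, 10 of 20 probe sets rose, 7 fell and 3 did not pass (adjusted p = 0.0625), and 10 rose and 8 fell adjusted over the list alone. The potassium-proton antiporter genes yhaT and yhaU (now khtT and khtU) were at 3.43 ± 0.12 (adjusted p = 2.0e-14) and 3.19. The list's median was 0.54, and the list passed without pH 9.0 replicate 3 (median 0.32, adjusted p = 0.0450), without pH 7.0 replicate 4 (median 0.73, adjusted p = 0.0434), under quantile normalization (adjusted p = 0.0253) and with dim probe sets removed (adjusted p = 0.0125). For malate and C4-dicarboxylate metabolism, 3 of 20 probe sets rose, 8 fell and 9 did not pass (adjusted p = 0.121), and 3 rose and 8 fell adjusted over the list alone. The genes ywkA and ydbH were at -3.21 ± 0.28 (adjusted p = 1.7e-08) and -2.39, and yufR, at background in base, was 45.3-fold lower with the intergenic median as its level. Among acetoin, lactate and acetate genes, 4 of 17 probe sets rose, 6 fell and 7 did not pass (adjusted p = 0.691), and 4 rose and 6 fell adjusted over the list alone. Lactate dehydrogenase lctE and the lactate transporter gene lctP were at 3.17 ± 0.14 (adjusted p = 5.2e-13) and 2.72, while the acetoin regulator gene acoR was at -1.41. Among alcohol, aldehyde and formate dehydrogenases, 2 of 19 probe sets rose, 8 fell and 9 did not pass (adjusted p = 0.058), and 2 rose and 8 fell adjusted over the list alone. The 3 probe sets of yrhE were at -4.06 ± 0.08, -3.85 and -3.58, and its median log2 change was -0.04. The list passed without pH 7.0 replicate 1, 2 or 5 (adjusted p = 0.0445, adjusted p = 0.0490 and adjusted p = 0.0493), with only the 2 groups compared (adjusted p = 0.0493) and under quantile normalization (adjusted p = 0.0481). It moved away from a call with 1 value per gene (median 0.05, adjusted p = 0.379), with dim probe sets removed (adjusted p = 0.186), as deposited (median 0.21, adjusted p = 0.108) and without pH 9.0 replicate 3 (adjusted p = 0.0999).

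Calls of the motility, ATP synthase and SigM lists in base depended on the processing. For motility and chemotaxis, 10 of 56 probe sets rose, 6 fell and 40 did not pass (median log2 change 0.04, adjusted p = 0.139, adjusted p = 0.857 with an estimated correlation), and 10 rose and 4 fell adjusted over the list alone. The list was called when pH 9.0 replicate 3 was left out, with 31 higher and 5 lower (median 0.18, adjusted p = 2.9e-05). It was also called as deposited, with 43 higher and 2 lower (adjusted p = 3.1e-05), and under quantile normalization, with 45 higher and 3 lower (adjusted p = 1.7e-08). Removing dim probe sets gave a call as well (median 0.040, adjusted p = 0.0261). For the ATP synthase, none of 9 probe sets rose, 4 fell and 5 did not pass (median log2 change -0.30, adjusted p = 0.224, adjusted p = 0.809 with an estimated correlation), and 0 rose and 3 fell adjusted over the list alone. Its direction turned under quantile normalization, where 8 rose and 0 fell (median 0.20, adjusted p = 0.000476), while 1 rose and 7 fell without pH 9.0 replicate 3 (median -0.17). In the SigM regulon, 4 of 22 probe sets rose, 4 fell and 14 did not pass (median log2 change 0.06, adjusted p = 0.762, adjusted p = 0.923 with an estimated correlation), and 2 rose and 4 fell adjusted over the list alone. Quantile normalization called it, with 11 higher and 3 lower (adjusted p = 0.0356), and 9 rose and 4 fell without pH 9.0 replicate 3.

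**Figure D3:**
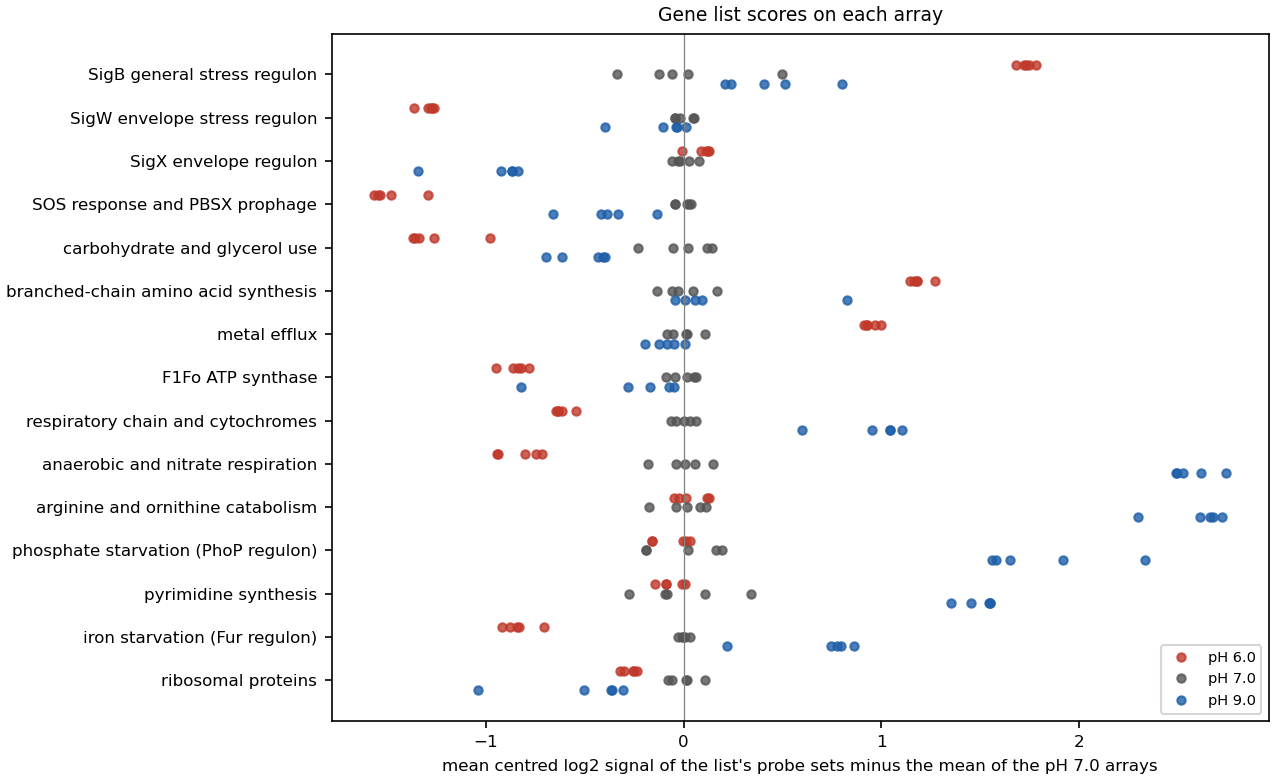
Mean centred log2 signal of each gene list relative to the mean of the pH 7.0 arrays, on the horizontal axis, for 15 lists, with 1 point per array and 5 arrays per pH. The scores of anaerobic and nitrate respiration are above those of pH 7.0 on all 5 arrays at pH 9.0 and below them on all 5 at pH 6.0, and pH 9.0 replicate 3 lies apart at 0.83 for branched-chain amino acid synthesis.

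The cultures at pH 9.0 were also set directly against those at pH 6.0. The phosphate-binding protein gene yqgG was at 6.5 to 9.2 at pH 6.0, below the median intergenic signal of every array, and with that median in place of its signal it was 85.2-fold higher at pH 9.0. The genes rocA, cydA, yqgJ and yqgI were 165-fold, 108-fold, 76.8-fold and 65.9-fold higher. These folds rest on dim signals at pH 6.0, such as 29.1 to 36.8 for cydA and 27.1 to 47.1 for rocA, against intergenic medians of 28.25 to 33.3. On the log2 scale rocA was at 7.37 ± 0.18 (SE, adjusted p = 4.4e-17). The pyruvate transporter genes ysbA and ysbB were 95.7-fold and 49.9-fold lower, yhbI and yhbJ 30-fold and 27.3-fold lower, and the metal exporter gene yvgW 27.8-fold lower, at -4.80 ± 0.11 (adjusted p = 1.6e-17). Signals for ysbA were 69.3 ± 74.7 at pH 9.0 and 4240.1 ± 216 at pH 6.0 (mean ± SD, n = 5), with 3 of the pH 9.0 arrays at or below their median intergenic signal. With 27.7 added to every signal, the log2 change of yqgG was 6.17 in place of 8.34, that of rocA 6.59, that of cydA 5.93, that of yqgJ 5.32, that of yqgI 5.26 and that of ysbA -5.88 in place of -6.58.

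In this comparison 2654 gene probe sets changed, 1084 higher and 1570 lower at pH 9.0, and 972 differed at least 2-fold, 540 higher and 432 lower. On the deposited scale, where each log2 change lay 0.19 higher, 1343 were higher and 1289 lower. Without pH 9.0 replicate 3, 3091 changed, and 2616 of the 2654 were again called in the same direction. Among genes of anaerobic and nitrate respiration, 16 of 16 probe sets rose, 0 fell and 0 did not pass, with a median of 3.01 (adjusted p = 9.2e-13), a call that held with an estimated correlation (adjusted p = 0.00505), and 16 rose and 0 fell adjusted over the list alone. In the respiratory chain, 21 of 31 probe sets rose, 3 fell and 7 did not pass (median log2 change 1.32, adjusted p = 7.8e-08, adjusted p = 0.406 with an estimated correlation), and 21 rose and 4 fell adjusted over the list alone. For arginine and ornithine catabolism, 6 of 7 probe sets rose, 1 fell and 0 did not pass (median log2 change 1.70, adjusted p = 0.000199, adjusted p = 0.131 with an estimated correlation), and 6 rose and 1 fell adjusted over the list alone. In the PhoP regulon, 10 of 21 probe sets rose, 1 fell and 10 did not pass (median log2 change 0.64, adjusted p = 0.00144, adjusted p = 0.329 with an estimated correlation), and 10 rose and 1 fell adjusted over the list alone, and without pH 9.0 replicate 3 its median was 0.35, with 10 higher and 5 lower. Among metal efflux genes, none of 15 probe sets rose, 7 fell and 8 did not pass (median log2 change -0.20, adjusted p = 0.00766, adjusted p = 0.196 with an estimated correlation), and 0 rose and 7 fell adjusted over the list alone. The metal efflux call ended under quantile normalization (adjusted p = 0.0723) and on the deposited scale (adjusted p = 0.0737), and the median was -0.32 without pH 9.0 replicate 3.

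Of the 38 lists, 22 were called between pH 9.0 and pH 6.0, 14 of them upward. In the SigW regulon 38 of 45 rose and 4 fell (median 1.41), in the Fur regulon 24 of 38 rose and 3 fell (median 0.60), and among antimicrobial peptides and polyketides 46 of 81 rose and 0 fell (median 0.49). For pyrimidine synthesis 12 of 13 rose and 0 fell (median 1.63), for carbohydrate and glycerol use 32 of 46 rose and 7 fell (median 0.86), and in the list of SOS and PBSX prophage genes 29 of 43 rose and 13 fell (median 1.70). For the ATP synthase 7 of 9 rose and 0 fell (median 0.64), for cysteine, methionine and sulfur metabolism 14 of 30 rose and 5 fell (median 0.38), and for the biofilm matrix 10 of 22 rose and 0 fell (median 0.32). For nitrogen limitation 9 of 24 rose and 2 fell (median 0.02), with a mean of 0.62 and, with 1 value per gene, a median of -0.10 and no call (adjusted p = 0.127). When pH 9.0 replicate 3 was left out, 10 of these rose and 8 fell (median 0.08), and the medians of the biofilm matrix and PerR lists were 0.22 and -0.17. Downward, 2 of 44 rose and 39 fell (median -1.10) in the SigB regulon, 0 of 18 rose and 18 fell (median -1.03) in the SigX regulon and 1 of 22 rose and 15 fell (median -0.45) in the SigM regulon. Among alcohol, aldehyde and formate dehydrogenases 2 of 19 rose and 13 fell (median -0.70), among decarboxylases 0 of 8 rose and 8 fell (median -0.87), for branched-chain amino acid synthesis 0 of 11 rose and 10 fell (median -0.92), and in the PerR regulon 0 of 13 rose and 7 fell (median -0.32). The adjusted p of these 17 lists ran from 3.4e-14 for SigW to 0.0285 for sulfur metabolism, and from adjusted p = 0.0957 to adjusted p = 0.666 with an estimated correlation. Adjusted over the list alone the counts were the same, except that 25 rose in the Fur regulon, 45 among antimicrobial peptides and 8 for the biofilm matrix, and 16 fell in the SigM regulon. Quantile normalization ended the calls of SigM (adjusted p = 0.0616), PerR (adjusted p = 0.182) and the biofilm matrix (adjusted p = 0.182), and values as deposited without pH 9.0 replicate 3 ended that of PerR (adjusted p = 0.0928).

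Changes at both extremes were set against each other next. Of 1215 gene probe sets that changed at both pH 6.0 and pH 9.0 relative to pH 7.0, 715 moved in the same direction and 500 in opposite directions. The split was 1206 and 783 without pH 9.0 replicate 3 and 981 and 507 on the deposited scale. Under quantile normalization it was more even, at 874 and 724, so the excess of shared directions depends on the scaling. Higher at both were 322, among them yvrK (now oxdC), oxalate decarboxylase, at 2.46 ± 0.17 in acid and 2.05 ± 0.17 in base, and opuCA, of a compatible solute transporter, at 2.31 and 2.02. Lower at both were 393, including ydbH, mtlA, mtlD and yyzE, with ydbH at -2.72 ± 0.13 and -2.39 ± 0.13 and yyzE at -1.97 and -3.01. Higher in acid and lower in base were 305, led by ysbA at 4.37 and -2.21, ynfC at 2.23 and -2.13, and the formaldehyde detoxification genes yckG and yckF (now hxlA and hxlB), with yckG at 2.44 ± 0.08 and -2.13 ± 0.08. Lower in acid and higher in base were 195, led by yweB (now gudB), a glutamate dehydrogenase, at -2.74 ± 0.14 and 2.62 ± 0.14, rocA at -2.32 and 5.05, dhbE at -2.16 and 2.09 and ykuN at -2.01 and 2.06. The dim genes yyaC, asnH and ybdT also passed upward at both. At pH 7.0 yyaC and asnH were below the intergenic median on all 5 arrays. With that median as the pH 7.0 level the ratios were 0.561 and 0.955 in acid and 1.54 and 0.948 in base, so only yyaC in base was higher by this measure. On pH 9.0 replicate 3 the centred log2 signal of yyaC was -0.86, against -4.35 to -3.51 on the other pH 9.0 arrays. Its log2 change in base went from 4.08 to 3.49 without that array, so whether yyaC rose in base is open. With 27.7 added yyaC no longer passed in acid (adjusted p = 0.303), ybdT was at 2.03 and 0.80, yvrK at 1.81 and 1.45, and rocA in acid at -1.73.

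Both comparisons share the pH 7.0 arrays, which ties their chance values together. In 100 simulations of unchanged groups against shared controls, the limma fit called no probe set at both extremes. With no changed genes hardly any call can arise, so this gives no expected overlap for genes that did change. Independent lists of these sizes would share 246 higher at both, 369 higher in acid and lower in base, 186 in the reverse class and 278 lower at both. When the 5 control arrays were divided between the comparisons in 20 ways, the median counts were 183.5, 184.5, 158.5 and 286. These counts come from separate fits with fewer arrays, so they also reflect a different power to call changes. The correlation of the log2 changes across genes was 0.181, against a simulated 0.501, and their covariance was 0.129, against a simulated 0.0336. The difference in covariance was 0.0952, and with divided controls the median covariance was 0.116. Without pH 9.0 replicate 3, 1989 probe sets changed at both.

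**Figure D4:**
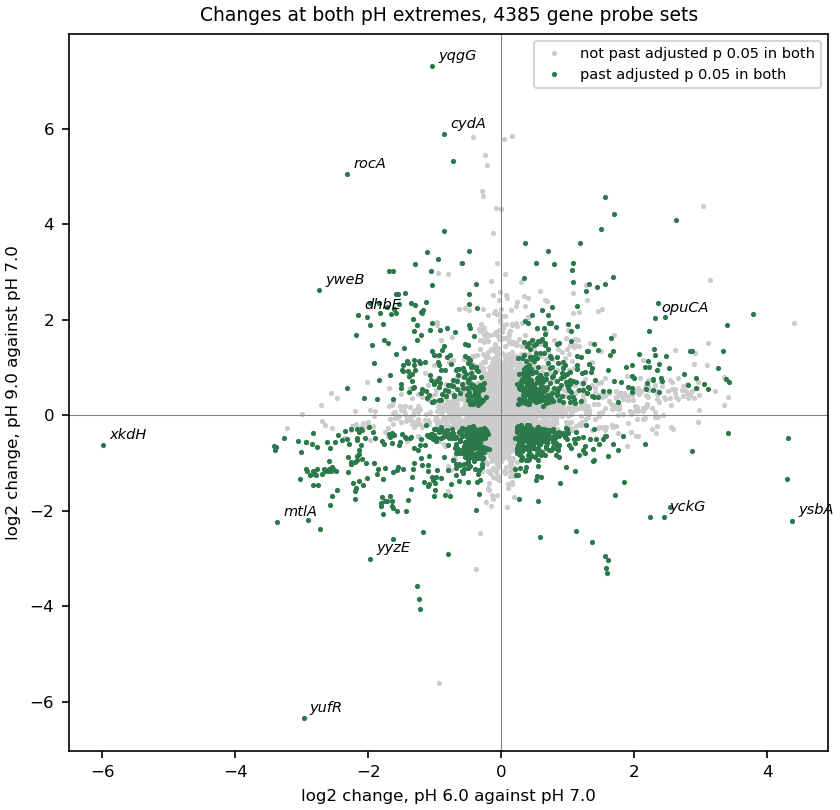
Log2 change at pH 6.0 against pH 7.0 on the horizontal axis and at pH 9.0 against pH 7.0 on the vertical axis for 4385 gene probe sets, 1 point each. The 1215 probe sets past the threshold in both comparisons are in green, with rocA at -2.32 and 5.05 and ysbA at 4.37 and -2.21.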

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

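Of the tests of explanations, those of the scanner background and of a wrong label were chosen only after the result was seen, while that of genomic DNA was not. For each value, the gap between the highest or lowest array of a group and its nearest neighbour was divided by the range of the group's 5 arrays, and ratios above 0.71, the 95 percent limit of Dixon's test, are listed. Chance gives about 1 in 20 groups.

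The array of pH 9.0 replicate 3 stood apart from the other pH 9.0 arrays in its 5th percentile of gene signal (ratio 0.972), its median intergenic signal (0.936) and its median log2 gene signal (0.786). Its rise over the other pH 9.0 arrays had a median of 153.7 on 303 intergenic probe sets of one strand and 143.35 on 303 of the other, a ratio of 0.933, and of 144.5 on the dimmest 25 percent of gene probe sets. A rise alike on both strands is what genomic DNA in the hybridised sample would give, so DNA may be the source. The 27 foreign control probe sets moved by -0.3, which argues against a raised scanner background, and over the brightest 25 percent of genes its lowest correlation with its own group exceeded its highest with any other group by 0.0967 (0.981 against 0.884), which argues against RNA of another pH under this label. Other sources of an additive signal, such as labelling or washing of this array, stay open, and no biological explanation was tested. At pH 6.0, replicate 1 stood apart in its median intergenic signal (ratio 0.911), at 33.3 against 28.25 to 28.7.

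Among 38 list scores, 22 set pH 9.0 replicate 3 apart from its group. It was the highest array for alcohol, aldehyde and formate dehydrogenases (0.802), competence (0.881), sporulation initiation and sporulation sigma factors (0.892), biofilm matrix (0.924), arginine synthesis (0.874), cysteine, methionine and sulfur metabolism (0.750), branched-chain amino acid synthesis (0.841) and tryptophan and histidine synthesis (0.742). It was the lowest for decarboxylases and polyamine synthesis (0.798), tricarboxylic acid cycle (0.748), glycolysis (0.735), iron starvation (0.814), peroxide stress (0.802), SigW envelope stress regulon (0.716), SigX envelope regulon (0.831), SigM envelope stress regulon (0.79996), heat shock proteins (0.806), motility and chemotaxis (0.775), purine synthesis (0.828), arginine and ornithine catabolism (0.742), fatty acid and phospholipid synthesis (0.852) and ribosomal proteins (0.731). At pH 6.0, replicate 5 was highest for respiratory chain and cytochromes (0.718) and carbohydrate and glycerol use (0.724) and lowest for thiol, quinone and superoxide stress (0.734). Replicate 2 was lowest for the SigW (0.714) and SigX (0.719) regulons, and replicate 3 highest for branched-chain amino acid synthesis (0.732). At pH 7.0, replicate 3 was highest for cysteine, methionine and sulfur metabolism (0.870).

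Of 157 named probe sets per group, 53 set pH 9.0 replicate 3 apart, 14 set an array apart at pH 6.0 and 10 at pH 7.0. It was the highest of its group for ysbA (0.840), ysbB (0.781), ybdT (0.713), yosK (0.720), yflS (0.723), yrhE probe set 1 (0.810), yhbI (0.769), ywkA (0.795), czcD (0.756), yjgD (0.774), ilvC (0.843), yciA (0.721), yciB (0.819), yciC (0.873), ydfN (0.772), ysnF (0.779), yyaC (0.758), yvrK (0.928) and xkdA (0.770). It was the lowest for xkdJ (0.716), rocA (0.819), cydD (0.964), atpC (0.713), atpI (0.749), yqfV (0.847), ykuN (0.776), ydjH (0.769), yqjL (0.830), lytD (0.810), srfAA probe set 7 (0.780), purK (0.732), purE (0.729), yjbW (0.803), rpsP (0.833), rpsB (0.847), bglH (0.722), yhaU (0.853), psd (0.776), pssA (0.741), ptsG (0.769), ptsI (0.863), ptsH (0.793), katA (0.960), ygaG (0.809), yvaB (0.829), yvyD (0.915), htrA (0.726), rocD (0.880), nasD (0.787), nasE (0.742), yweB (0.745), yjlC (0.796) and yjlD (0.746). At pH 6.0, replicate 1 was highest for ykzA (0.721). Replicate 1 was lowest for yfkE (0.783) and purE (0.732). Replicate 2 was highest for yhbI (0.721). Replicate 2 was lowest for yqgJ (0.761) and rpsS (0.788). Replicate 3 was highest for ylnD (0.766). Replicate 3 was lowest for mtlA (0.722) and ycdH (0.715). Replicate 4 was lowest for pyrAA (0.768). Replicate 5 was highest for ydjG (0.913). Replicate 5 was lowest for ytiA (0.832), hrcA (0.738) and yckG (0.727). At pH 7.0, replicate 1 was lowest for levD (0.717) and yyaC (0.750). Replicate 2 was lowest for xkdX (0.748) and yvaX (0.774). Replicate 3 was highest for czcD (0.793) and xre (0.724). Replicate 3 was lowest for rocA (0.866), hrcA (0.897) and tagC (0.747). Replicate 4 was highest for yfkE (0.785).

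Probe sets for intergenic regions, which lie outside the comparisons of genes, changed too. Of 606, 112 changed at pH 6.0 against pH 7.0 (59 higher), 150 at pH 9.0 against pH 7.0 (111 higher) and 145 at pH 9.0 against pH 6.0 (96 higher). Without pH 9.0 replicate 3 these counts were 248 (150 higher), 212 (136 higher) and 241 (118 higher, 123 lower), so the excess of rises at pH 9.0 against pH 6.0 was not kept.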

How the results depend on the processing

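Leaving out arrays of the group outside a comparison, 1 value per gene, and values as deposited without pH 9.0 replicate 3 were chosen only after the result was seen. Array weights raised the probe sets changed at pH 6.0 against pH 7.0 to 3079 and those changed at both extremes to 2215, and gave pH 9.0 replicate 3 a weight of 0.0273. A 2-fold minimum left 662, 552 and 972 probe sets, and 194 at both extremes. With 1 array left out, the count at both extremes ran from 1027 (without pH 7.0 replicate 1) to 1989 (without pH 9.0 replicate 3), and values as deposited without that array gave 2001. The estimated correlation left 2 of 56 list calls, and was not estimated again without pH 9.0 replicate 3. Among results called in at least 1 setting, and for single genes, directions turned at pH 9.0 against pH 7.0 under quantile normalization for the ribosomal list (median -0.0072, adjusted p = 0.842) and the ATP synthase list (median 0.20, adjusted p = 0.000476), for acetoin, lactate and acetate metabolism at pH 6.0 under fry (median -0.16, adjusted p = 0.0208) and for xre at pH 6.0 on values as deposited (0.0011, adjusted p = 0.993); the cause was not tested. Of 195 named results for genes, 191 kept direction and side of the threshold under quantile normalization, 194 with the pseudocount, 194 as deposited, 192 with each array left out, 194 with only the 2 groups compared and 195 without the intensity trend; of 163 that the dim filter left, 163 did. Of all 114 list tests, 80 did so under quantile normalization, 103 as deposited, 112 with the pseudocount, 102 without dim probe sets, 99 with each array left out, 107 with only the 2 groups compared, 87 under fry, 110 with 1 value per gene and 60 with the estimated correlation. Quantile normalization ended 9 calls and added 12, leaving out single arrays ended 1 and added 9, and fry ended 2 and added 22. Tests with no call in either setting turned direction in 13 cases under quantile normalization, among them glycolysis at pH 6.0 (median from -0.21 to 0.020), and in 6 as deposited. Signal over background limits dim genes, since 27.7 is close to the median intergenic signal of 33.8.

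With the replicate number as a replicate block, 1921, 2284 and 2620 probe sets changed, 1134 at both extremes, and 56 list calls were made; each of the 195 gene results and 114 list tests kept its direction and side of the threshold. Deviations from group means correlated above 0.1 in 3 of 15 pairs of same-numbered arrays (from -0.41 to 0.19), and 2 of 15 arrays correlated best with their own number in another group, so the numbers were not taken to pair the cultures.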

Other observations

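Of the tests of explanations here, those of the SOS response, of a minority of cultures, of ResD and of the raised floor were chosen only after the result was seen, and so was the choice of lists without a call. In base, genes for antimicrobial peptides and their immunity changed in both directions while the list was not called. Of 81 probe sets, 37 rose, 22 fell and 22 did not pass at pH 9.0 against pH 7.0 (median log2 change 0.48, adjusted p = 0.205), and 38 rose and 22 fell adjusted over the list alone. The balance depended on the scaling, and with dim probe sets removed the test pointed downward (median -0.92, adjusted p = 0.632). Under quantile normalization 19 rose and 24 fell (median -0.027, adjusted p = 0.831), as deposited the test pointed downward (median 0.72, adjusted p = 0.828), and without pH 9.0 replicate 3 the median was 0.28. With 1 value per gene the list was called (median 0.71, adjusted p = 3.0e-05). The subtilosin gene sbo was at 3.41 ± 0.20 (adjusted p = 3.9e-11), or 2.74 with the pseudocount. Its transport gene ywhM (now albG) and yvaX (now sdpB), of the sporulation delaying toxin, were not above the intergenic median on any pH 7.0 array, and with that median as their level they were 4.21-fold and 1.92-fold higher. For thiol, quinone and superoxide stress at pH 6.0, 12 of 22 rose and 2 fell (median 0.35, adjusted p = 0.0638), and 13 rose and 2 fell adjusted over the list alone. The peroxide resistance genes ykzA and yklA (now ohrB and ohrA) were at 2.27 ± 0.20 (adjusted p = 1.1e-08) and -0.90, and yqjM (now namA) at 1.85. That list passed without pH 6.0 replicate 5 (adjusted p = 0.0462), without pH 9.0 replicate 3 (adjusted p = 0.0392), under quantile normalization (adjusted p = 0.00598) and as deposited (adjusted p = 0.00616). In base 6 of 22 rose and 8 fell (median -0.12, mean 0.10, adjusted p = 0.936), and 6 rose and 9 fell adjusted over the list alone, with the quinone response genes yodD (now mhqD) at 1.96, yvaB (now azoR2) at 1.93 and ydfN (now mhqN) at 1.91, the last at 1.32 with the pseudocount.

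Zinc and manganese uptake genes changed one by one. In acid 3 of 15 rose and 2 fell (adjusted p = 0.817), 2 and 2 adjusted over the list alone, with ytiA (now rpmEB), a zinc-free ribosomal protein, at 1.25, the zinc-binding transporter gene ycdH (now znuA) at -0.68 and the zinc repressor gene yqfV (now zur) at -0.32. The change of yqfV did not pass without pH 6.0 replicate 2 or 5 or pH 7.0 replicate 1 or 2 (adjusted p = 0.0661, adjusted p = 0.0704, adjusted p = 0.0717 and adjusted p = 0.0526). In base 5 of 15 rose and 5 fell (adjusted p = 0.432), 5 and 5 adjusted over the list alone, with yciC at 1.88, or 1.16 with the pseudocount. The genes yciA and yciB were not above the intergenic median on any pH 7.0 array, and with that median as their level they were 2.73-fold and 1.8-fold higher. These rises lean on pH 9.0 replicate 3, where yciA, yciB and yciC had centred log2 signals of -0.94, -1.13 and -0.32. On the other pH 9.0 arrays their highest values were -2.51, -3.20 and -2.28. The list passed under quantile normalization, with 8 higher and 0 lower (adjusted p = 0.0132). Among lists with no call in either comparison against pH 7.0 with all arrays, given for pH 6.0 and then pH 9.0, 5 rose and 4 fell (adjusted p = 0.993) and 2 rose and 8 fell (adjusted p = 0.128) for the tricarboxylic acid cycle, 1 rose and 5 fell (adjusted p = 0.204) and 7 rose and 6 fell (adjusted p = 0.524) for competence, and 1 rose and 3 fell (adjusted p = 0.64) and 8 rose and 2 fell (adjusted p = 0.128) for sporulation. For the biofilm matrix 2 rose and 9 fell (adjusted p = 0.0785) and 6 rose and 2 fell (adjusted p = 0.128), for arginine synthesis 0 rose and 3 fell (adjusted p = 0.139) and 0 rose and 3 fell (adjusted p = 0.591), and for tryptophan and histidine synthesis 10 rose and 0 fell (adjusted p = 0.0794) and 8 rose and 7 fell (adjusted p = 0.591). Adjusted over the list alone the counts in the same order were 5 and 4 then 2 and 8, 1 and 4 then 7 and 6, 1 and 3 then 7 and 2, 2 and 9 then 6 and 2, 0 and 3 then 0 and 2, 10 and 0 then 8 and 7. Adjusted over all genes, with pH 9.0 replicate 3 left out, they were 7 and 8 then 6 and 8, 4 and 7 then 7 and 7, 6 and 6 then 7 and 8, 2 and 11 then 6 and 3, 0 and 7 then 0 and 7, 12 and 1 then 8 and 7. That array had a score of 1.01 for sporulation, against 0.21 to 0.29 on the other pH 9.0 arrays, and the list's median went from 0.20 to -0.06 without it. The biofilm list was called at pH 6.0 without that array (adjusted p = 0.0368), under quantile normalization (adjusted p = 0.0361) and as deposited without that array (adjusted p = 0.0499). Arginine synthesis was called under quantile normalization at both pH values (adjusted p = 0.0461 in each). Tryptophan and histidine synthesis was called at pH 6.0 as deposited without that array (adjusted p = 0.0488) and with dim probe sets removed (adjusted p = 0.0476). For fatty acid synthesis in base 0 rose and 9 fell (adjusted p = 0.0619), and 0 and 6 adjusted over the list alone, and it was called with 1 of pH 7.0 replicates 4 and 5 or of the pH 9.0 replicates other than replicate 3 left out (adjusted p from 0.0314 to 0.0491). With that replicate left out, 0 rose and 8 fell (adjusted p = 0.185). Between pH 9.0 and pH 6.0 the same list had 3 higher and 5 lower (adjusted p = 0.643), 11 higher and 5 lower without pH 9.0 replicate 3 (median 0.26, adjusted p = 0.0868), and 11 higher and 1 lower under quantile normalization (adjusted p = 0.0103). It was called as deposited without that array, with 11 higher and 1 lower (adjusted p = 0.036).

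The PBSX prophage genes fell together at pH 6.0. All 25 late prophage probe sets were lower, with a median log2 change of -2.69. Loss of the prophage is argued against by xre and xkdA, outside the late operon, whose lowest signal at pH 6.0 was 139.2, above intergenic medians of 28.25 to 33.3, with log2 changes of -0.05 for xre (adjusted p = 0.804; 0.0011 on values as deposited) and 0.31 for xkdA (adjusted p = 0.195, and adjusted p = 0.00137 without pH 9.0 replicate 3). A weaker SOS response is argued against by 12 SOS probe sets outside the prophage, 9 of them higher and 0 lower, with a median of 0.79, and induction in a minority of the pH 7.0 cultures by a gap of 2.36 between the lowest pH 7.0 and highest pH 6.0 array in mean log2 value of the late genes. A difference between the cultures that follows pH by a route other than SOS remains a hypothesis and may hold, though a shared history of the cultures at 1 pH was not tested.

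The list of anaerobic and nitrate respiration rose at pH 9.0 in aerated cultures. The raised floor of pH 9.0 replicate 3 is argued against, as the list's median was 1.88 with and without that array. Oxygen limitation acting through the regulator ResD may contribute. Of 13 other ResD targets, 13 rose, from 0.37 for resA to 3.41 for sbo, with a median of 0.744 (0.89 without that array). Apart from ctaA they belong to the subtilosin and cytochrome maturation operons, and genes of 1 operon do not count as independent. Other regulators also share these genes. Relief of repression by Rex stays undecided. Its test left out the list's own members, among them cydA, cydB and lctE, whether or not Rex acts on them. It covered only 3 Rex targets and left out all others, so its result cannot be weighed against that of the 13 ResD targets. The 3 were ywcJ, yjlC and yjlD, at 3.27, -0.71 and -0.56 with a median of -0.56, and ywcJ was at 2.28 with the pseudocount. That median met the bound set beforehand against Rex, but members passed in both directions, a median over 3 such members decides little, and the rule that left it open was set after the value was seen.

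The counts of changed probe sets were far higher for the real grouping than for other splits of the arrays. In a model of the 2 groups alone, the real split of pH 6.0 and pH 7.0 arrays gave 2901 and the highest of the others 1, that of pH 9.0 and pH 7.0 gave 1993 against 9, and that of pH 9.0 and pH 6.0 gave 2457 against 0. In each comparison, 1 of the 100 splits drawn, the real one, gave as many. The other splits mix arrays of the 2 groups, so the difference between the groups enters their spread. The test therefore cannot tell how many of the calls are false. Nor can it separate pH from anything else that differed between the groups.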
